A study of Oryza sativa with 6 samples.

How the data were processed

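RNA was measured in rice seedlings 11 days old, grown on agar medium with sucrose under 14 h of light and 10 h of dark. Each of 6 samples was hybridized to its own Affymetrix Rice Genome Array. 3 samples came from a T-DNA mutant of CHR729, a CHD-type chromatin remodelling gene, and 3 from wild-type seedlings of the cultivar Hwayoung. The labels call the samples biological replicates and give no pairing, day or batch.

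The deposited values are probe set intensity on a linear scale, which the authors made with MAS5. The version, the background and scaling settings and the scaling target are not given in the sources used here, and detection calls are not used here. Median signals per array lay between 67.6 and 71.1. For arrays with 3 replicates per group, the number of arrays limits the precision.

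Of 57381 probe sets, 123 Affymetrix control probe sets (identifiers with the AFFX prefix) were left out and 57258 were tested. No filter on dim probe sets was used. Signals were transformed as log2(signal + 32), which damps differences between dim probe sets. The mutant and wild-type groups were compared with a linear model and moderated test in limma 3.58.1 under R 4.3.3 (lmFit, then eBayes with an intensity trend), 2-sided. P values were adjusted by the Benjamini-Hochberg method over all tested probe sets, with a threshold of 0.05. Log2 differences are mutant minus wild type throughout, with the standard error (SE) of the model; signals are means with the standard deviation (SD) of 3 arrays. Folds are the antilog of these differences, so the offset lowers them for dim probe sets. A rank or permutation test of 3 against 3 arrays cannot give a 2-sided p below 0.1, so none was the main test of single genes. This choice of test, the alternatives for the probe set counts and the first set of gene lists were fixed before the data were examined.

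Probe sets were joined to genes with the public annotation of the array. 22436 of the tested probe sets named 1 gene, 95 named several genes and 34727 named none. Together they covered 17905 genes, of which 2446 had a gene name rather than a locus number in the rice gene table (assembly ASM3414082v1). No table paired a probe set with CHR729, so its transcript is not analysed here. Tables were joined with pandas 2.3.3 under Python 3.11.15, and plots were drawn with matplotlib 3.10.9.

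Gene lists were tested with camera from limma, a competitive test against all other genes with a preset inter-gene correlation of 0.01, using the brightest probe set per gene and lists of 5 or more measured genes. P values were adjusted within each set of lists. The first set had 26 lists, written as patterns for gene descriptions and symbols. The annotation gave no descriptions, and 6 of these lists had enough members. Lists of the same themes were therefore rebuilt from gene symbols, of which 22 could be tested, and 23 lists of further themes were added. The rebuilt and the further lists were written after the gene-name tables were read and before the groups were compared. Each list was tested again with an estimated inter-gene correlation and with fry, a self-contained test of whether the members moved, on balance, one way.

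Named genes followed a rule fixed before the data were examined, except that a gene name stood in for the gene description it asked for. It took the 12 largest rises and the 12 largest falls among probe sets past the threshold that named 1 gene with a name, had no overlap between the groups and lay at or above the median signal in the brighter group. It also took up to 4 members with the lowest p from each list. That part was applied to the rebuilt and the further lists instead of the first set. It was shortened after the values had been seen. A rebuilt list that missed the threshold gave at most 2 members, and a further list that missed it gave none. Any other feature that is named was chosen after its values were seen.

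The procedure was tested on simulated data with 200 changed probe sets among 57258, under 2 models of the variance. With the first model, limma called 25 of 50 probe sets changed 1.5-fold and 50 of 50 at 2-fold, 4-fold and 8-fold, and 23 of its 207 calls (11.1%) were unchanged probe sets. The second model, drawn from limma's own trend and prior, was added after those false calls were seen. It gave 28, 47, 50 and 50 of 50 at the same changes, and 7 of 190 calls (3.68%) were unchanged. The first model exceeds the nominal 5% and the second meets it by its construction, so the error rate of the real calls may lie above the threshold. Under both models camera called 0 of 20 unchanged lists at the threshold and called the shifted list of 30 genes. The simulated probe sets varied independently, so this does not test camera on lists whose members vary together.

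The alternatives were offsets of 1 and 128, quantile normalization, subtraction of each array's median, leaving out the 40% dimmest probe sets, no intensity trend, array weights, a block by replicate number, leaving out probe sets with the suffix s or x, leaving out each array, a change of at least 2-fold beside the adjusted p, and a SAM-type test (20 label assignments, q-value of 5%) on log2 and on linear signals. For lists they were the estimated correlation, fry and the mean over the probe sets of a gene. All other splits of the 6 arrays into groups of 3 were also fitted.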

Results

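Transcript levels were measured on 6 rice arrays, 3 from CHR729 mutant seedlings and 3 from wild-type seedlings. Each array gave a signal for 57258 tested probe sets, with medians between 67.6 and 71.1. Means trimmed by 2%, taken over all 57381 probe sets with the controls, lay between 192.6 and 202.4. The arrays separated by genotype along the first principal component, which held 59.9% of the variance. Mutant arrays scored between -39.5 and -22.1 on it and wild-type arrays between 20.8 and 36.1. Correlations of log2 signals across probe sets, which are not independent replicates, were 0.992 to 0.996 between mutant arrays, 0.988 to 0.99 between wild-type arrays and 0.973 to 0.986 between the groups.

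The comparison of mutant with wild type asked which transcripts differ in seedlings that carry a T-DNA mutation in CHR729. LOX1.1, a lipoxygenase gene, rose 8.29-fold (log2 difference 3.05, SE 0.33, n = 3 per group) and OsJAZ2, a gene for a repressor of jasmonate responses, rose from a signal of 6.68 ± 3.77 (SD), which is dim against the array medians, to 126.7 ± 24.1, whereas the repressor genes OsJAZ13 and OsJAZ3 (LOC4331832) fell by 2.36 (SE 0.51) and 2.10 (SE 0.45) on the log2 scale. Transcription factor genes with large falls were DREB1B, DREB1G, OsbHLH148, OsWRKY24, OsMYB2 and the heat shock factor gene OsHsf-07, with log2 differences from -2.23 to -1.77. OsWRKY71 had -1.71 and -0.80 in its 2 probe sets. DREB1B and OsbHLH148 also differed several-fold between arrays of 1 genotype. Of the 12 named largest falls, 8 had the same array order by replicate number in both genotypes, and the cause was not tested. Of 26 measured genes matched by ribosomal protein symbols, 18 rose, with a list median of 0.41 on the log2 scale, and the list passed camera at adjusted p = 7.40e-08, against adjusted p = 0.86 with an estimated correlation. Genes of calmodulin-like calcium sensors, such as CML15 and CML10, were among the largest falls.

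In all, 3140 probe sets rose and 2532 fell, which is 9.91% of those tested, and 55.4% of the 5672 changed probe sets rose. The median log2 difference was 0.48 among those that rose and -0.52 among those that fell. Changes of at least 2-fold were seen in 208 probe sets that rose and 249 that fell. The groups did not overlap in 3136 of the rising and 2515 of the falling probe sets, and in 27.1% of all probe sets, where chance gives 10%. Of the 22436 tested probe sets that named 1 gene, 2235 rose and 1831 fell, a larger share than among all probe sets. The gene lists hold only such probe sets, so counts of list members compare with this share and not with 9.91%. The changed probe sets that named 1 gene belonged to 2055 genes that rose and 1681 that fell. Among these, 7 genes were counted in both because their probe sets went opposite ways. The counts changed when an array was left out. Without mutant replicate 2 they were 1358 and 916, without mutant replicate 3 1716 and 1071, and without wild-type replicate 2 1779 and 1356. Without wild-type replicate 3 they were 3511 and 2838, and the cause of these changes was not tested. The submitters stated 254 genes up and 345 down at a q-value of 5%, counted with SAM. Those are counts of genes, of which more fell than rose, whereas more probe sets rose here. The SAM-type test at the same q-value called 4599 rising and 3425 falling probe sets on log2 signals. On linear signals it called 3337 and 1485, so the counts exceeded the stated ones on either scale. The scale of the values the submitters tested, and whether a change of a certain size was also required, are not given in the sources used here.

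**Figure D1:**
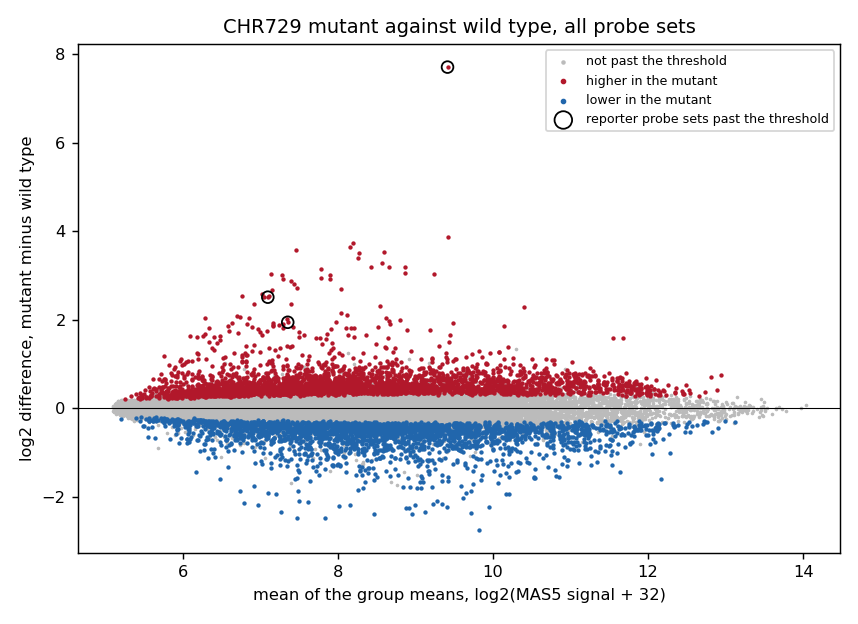
Log2 difference between CHR729 mutant and wild type (y axis) against the mean of the group means on the log2(MAS5 signal + 32) scale (x axis), 1 point per probe set. Red points are the 3140 probe sets that rose, blue points the 2532 that fell, and circles mark 3 reporter probe sets that rose.

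Pir7b, an esterase gene first found as induced by Pseudomonas, rose from 82.6 ± 15.97 in wild type to 1022 ± 213 in the mutant (signal, SD, n = 3; log2 difference 3.19, SE 0.15, adjusted p = 1.21e-06). LOX1.1 rose from 130.9 ± 19.3 to 1472 ± 815 (3.05, SE 0.33, adjusted p = 0.000497). OsJAZ2 rose by 2.03 (SE 0.11, adjusted p = 3.63e-06), a size that depends on the offset because its wild-type signal was dim: the log2 difference was 4.15 with the lower alternative offset and 0.92 with the higher one. mfs1 rose 3.06-fold, and OsAOX1A, which encodes the mitochondrial alternative oxidase, rose 2.79-fold, from 114.4 ± 26.6 to 373.8 ± 48.9. The small heat shock protein genes OsHsp24.1 and OsHsp26.2 rose 2.59-fold and 2.23-fold. OsCIN2, a cell wall invertase gene, rose 2.42-fold, and OsCCD8a, a carotenoid cleavage dioxygenase gene of the strigolactone pathway, rose 2.32-fold. OsMEL1, a germline Argonaute gene, rose 2.29-fold, from 39.6 ± 1.99 to 133.9 ± 31.8. The offset makes the folds of OsAOX1A and OsMEL1 smaller than the ratios of their signals. OC-X and the chitinase gene OsChia1a each rose 2.24-fold. Adjusted p for these 12 genes was at most 0.00374, and each passed the threshold in every limma alternative that kept its probe set, whereas the SAM-type test called 12 of them on log2 signals and 10 on linear signals, LOX1.1 and OsChia1a being missed.

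OsJAZ13 fell from 1439 ± 936 in wild type to 256.7 ± 190 in the mutant (log2 difference -2.36, SE 0.51, adjusted p = 0.0165). DREB1B, a cold-response factor gene, fell from 1666 ± 1065 to 310.8 ± 171 (-2.23, SE 0.45, adjusted p = 0.0122), and DREB1G of the same family fell by 1.80. OsJAZ3 at LOC4331832 fell from 1323 ± 477 to 332.8 ± 280.1 (-2.10, SE 0.45, adjusted p = 0.0151), whereas a second gene with the symbol OsJAZ3, LOC4345625, had a log2 difference of 0.25 (adjusted p = 0.14). OsHsf-07 fell from 2293 ± 121 to 587 ± 175 (-1.94, SE 0.16, adjusted p = 9.25e-05). The helix-loop-helix factor gene OsbHLH148 fell by 1.92, the WRKY factor genes OsWRKY24 and OsWRKY71 fell by 1.80 and 1.71 (by 0.80, adjusted p = 0.0471, in a brighter OsWRKY71 probe set), and OsMYB2 fell by 1.77 on the log2 scale. The calmodulin-like genes CML15 and CML10 fell by 1.76 and 1.57, and a dim CML10 probe set had a difference of -0.04 (adjusted p = 0.801). OsBURP16, a BURP-domain gene, fell from 7983 ± 354 to 2605 ± 304 (-1.61, SE 0.09, adjusted p = 5.99e-06). For 5 of these 12 genes the call rested on the full set of arrays: OsJAZ13, OsJAZ3 and OsbHLH148 missed the threshold without mutant replicate 2, without mutant replicate 3 and without wild-type replicate 2, OsbHLH148 also without wild-type replicate 1, and DREB1B and OsWRKY71 without wild-type replicate 2, with adjusted p between 0.0514 and 0.113. The log2 differences of the lost calls lay between -2.34 and -1.45. With the replicate number as a block all 12 falls passed. The SAM-type test called 12 of the falls on log2 signals and 3 on linear signals.

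**Figure D2:**
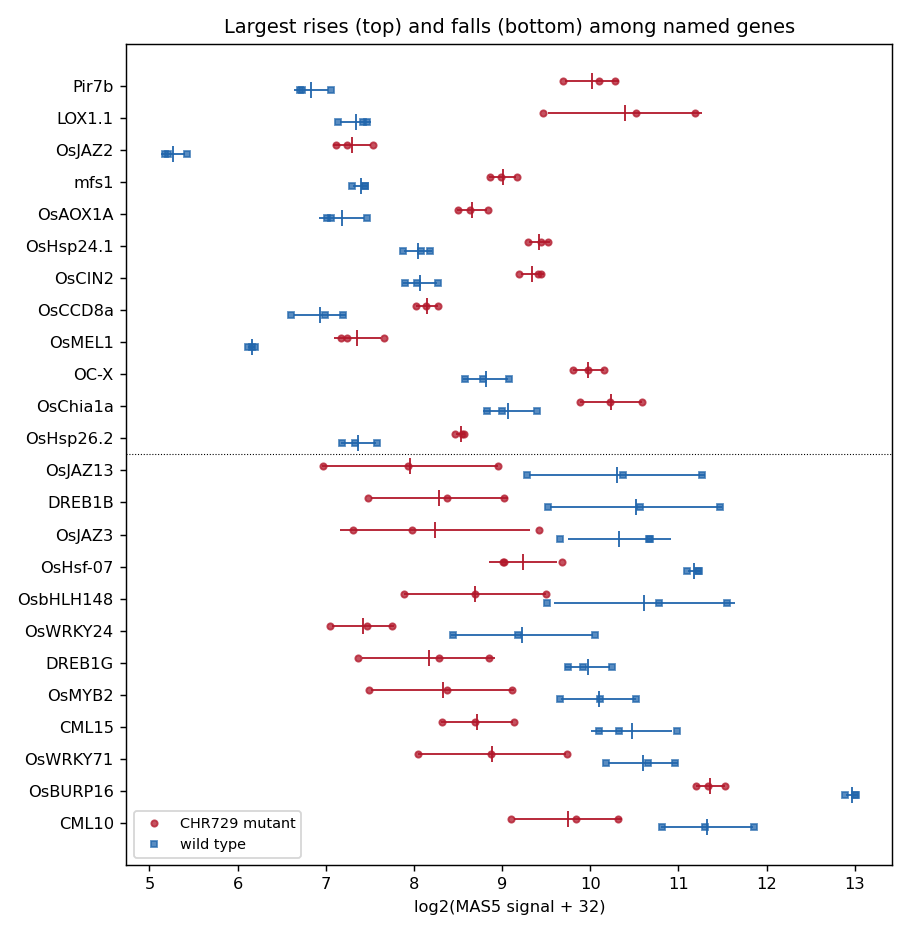
Signals of the 12 named genes with the largest rise (top) and the 12 with the largest fall (bottom) on the log2(MAS5 signal + 32) scale, with red circles for the 3 mutant arrays and blue squares for the 3 wild-type arrays. Vertical ticks are group means and horizontal bars the SD of 3 arrays; OsJAZ13 and DREB1B show a wide spread in both groups.

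The list written for cytosolic ribosomal proteins, parts of the translation machinery, had 18 of 26 members higher, and 23 when p was adjusted over the list alone. It also holds CL18 and CL27, known as chloroplast ribosomal protein genes, which did not pass and had log2 differences of -0.09 and 0.02. RPS26 rose from 1820 ± 151 to 3094 ± 136 (log2 difference 0.76, SE 0.09, adjusted p = 0.000884), RPL39B rose by 0.60 (SE 0.09), RPL7A-2 by 0.52 (SE 0.09) and RPS4 by 0.49 (SE 0.09). The Calvin cycle and photorespiration list had 6 of 13 members lower and 1 higher, or 8 and 1 when adjusted over the list alone, with a median of -0.31 (adjusted p = 0.0221, and adjusted p = 0.86 with an estimated correlation). FBPase, a fructose bisphosphatase gene, fell by 0.47 (SE 0.09), TPT, the triose phosphate translocator gene, fell by 0.48 (SE 0.10) and Fd-GOGAT, the ferredoxin-dependent glutamate synthase gene, fell by 0.48 (SE 0.12). Dim probe sets of TPT and Fd-GOGAT had 0.00 (adjusted p = 0.984) and -0.20 (adjusted p = 0.501) and did not pass. OsGLO4, a glycolate oxidase gene, rose by 0.38 (SE 0.09). Without wild-type replicate 3 this list had adjusted p = 0.104. These were the 2 of 22 rebuilt lists that passed camera, where 4 passed without mutant replicate 2, 4 without wild-type replicate 2 and 1 without wild-type replicate 3. No list passed with an estimated correlation or with fry, where the ribosomal list had adjusted p = 0.0523, and 5 had an unadjusted camera p under 0.05.

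4 of the further lists were shifted upwards. Of 61 cell cycle and DNA replication genes 22 rose and 3 fell (30 and 4 adjusted over the list alone), with adjusted p = 0.000758, and adjusted p = 0.477 with an estimated correlation. The replication protein gene OsRPA32 rose by 0.77 (SE 0.10), the cyclin genes CYCB2 (LOC4342121) and CYCA2-1 by 0.94 (SE 0.12) and 0.67 (SE 0.09), and the origin recognition gene OsORC4 by 0.91 (SE 0.12), with 0.24 (adjusted p = 0.0735) in a dim OsORC4 probe set. Of 32 genes for kinesins, motor proteins that move on microtubules, 13 rose (16 over the list alone), with adjusted p = 0.000758, and adjusted p = 0.499 with an estimated correlation. KIN5C rose by 0.63 (SE 0.10), OsNACK by 0.61 (SE 0.10), KIN14N by 0.60 (SE 0.09) and KIN10B by 0.59 (SE 0.10). Of 16 genes for growth-regulating and YABBY factors 4 rose (5 over the list alone), with adjusted p = 0.0162, and adjusted p = 0.477 with an estimated correlation. These were OsGRF6, OsGRF1, OsYAB5 and OsGRF8, with rises of 0.56 (SE 0.10), 0.49 (SE 0.10), 0.46 (SE 0.11) and 0.42 (SE 0.08). Of 20 genes for protein folding in the endoplasmic reticulum 2 rose and 1 fell (9 and 1 over the list alone), with adjusted p = 0.0272, adjusted p = 0.477 with an estimated correlation, and adjusted p = 0.0625 without wild-type replicate 3. OsPDIL2-1 and OsPDIL1-5, protein disulfide isomerase genes, rose by 0.45 (SE 0.11) and 0.36 (SE 0.10), and OsDjC27, dim in both groups (31 and 45.5), fell by 0.30 (SE 0.08).

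3 of the further lists were shifted downwards. Of 78 calcium signalling genes 16 fell and 2 rose (27 and 4 over the list alone), with adjusted p = 0.00702, and adjusted p = 0.477 with an estimated correlation. CML15 fell by 1.76 (SE 0.24), CML31 by 1.54 (SE 0.20), CML30 by 0.80 (SE 0.10) and CML18 by 0.76 (SE 0.12). Of 22 abscisic acid genes 4 fell (6 over the list alone), with adjusted p = 0.00702, and adjusted p = 0.477 with an estimated correlation. OsABF2, a bZIP factor gene, fell by 0.83 (SE 0.16), OsABIL1 fell by 0.55 (SE 0.12), the protein phosphatase gene OsPP2C09 fell by 0.53 (SE 0.12) and the protein kinase gene OsSAPK3 fell by 0.39 (SE 0.10). Of 47 chloroplast biogenesis and isoprenoid genes 11 fell and 2 rose (15 and 2 over the list alone), with adjusted p = 0.0135, and adjusted p = 0.477 with an estimated correlation. The plastid protease genes CLPD1 and CLPC2 fell by 0.82 (SE 0.12) and 0.66 (SE 0.10), DXR of the plastid isoprenoid pathway fell by 0.53 (SE 0.10), and PRIN2 rose by 0.55 (SE 0.09). In all 7 of the 23 further lists passed camera, none with an estimated correlation, 11 had an unadjusted p under 0.05 and 3 passed fry, namely cell cycle, protein folding and the heat shock factor list, which missed camera.

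**Figure D3:**
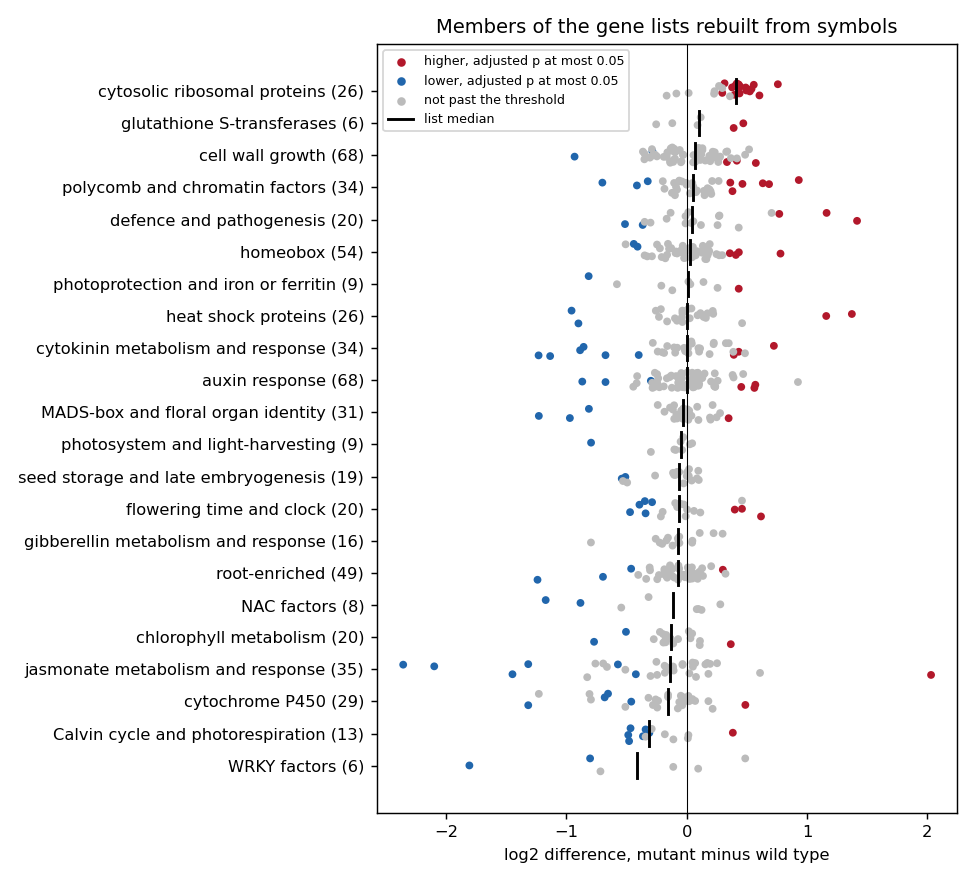
Log2 differences between mutant and wild type (x axis) for the members of the 22 gene lists rebuilt from symbols (y axis, number of genes in parentheses). Red and blue points are genes that rose or fell, grey points those that did not pass, and black bars list medians, the highest of which is 0.41 for cytosolic ribosomal proteins.

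The jasmonate list did not pass camera: of 35 members 6 fell and 1 rose (7 and 1 over the list alone), with adjusted p = 0.135. Its members that changed include OsJAZ2 and AOS at LOC4332121, an allene oxide synthase gene of jasmonate synthesis, which fell from 468.7 ± 1.96 to 170.1 ± 25.1 (log2 difference -1.32, SE 0.10, adjusted p = 6.39e-05). A second gene named AOS, LOC4334233, had -0.51 (adjusted p = 0.165), and AOS3 and AOS4 had 0.18 and 0.05 and did not pass. In the cytochrome P450 list 4 of 29 fell and 1 rose (6 and 1 over the list alone, adjusted p = 0.0702), AOS among them. OsKO5, dim in both groups, fell from 32.2 ± 15.2 to 7.35 ± 2.47 (log2 difference -0.68, SE 0.14), and the size of its fall depends on the offset. Of 6 WRKY genes 2 fell (2 over the list alone, adjusted p = 0.416), and of 8 NAC genes 2 fell (3 over the list alone, adjusted p = 0.595), OsNAC6 by 1.17 (SE 0.28) and OsNAC5 by 0.88 (SE 0.20). A further OsNAC6 probe set fell by 1.14 and a dim one had -0.07 (adjusted p = 0.705), and 2 dimmer OsNAC5 probe sets did not pass, with -0.38 (adjusted p = 0.217) and -0.48 (adjusted p = 0.0693). In the defence list 3 of 20 rose and 2 fell (4 and 2 over the list alone, adjusted p = 0.683), with LOC4351188, a chitinase gene, up by 1.42 (SE 0.20) from a dim wild-type signal of 37.5. Of 26 heat shock protein genes 2 rose and 2 fell (3 and 2 over the list alone, adjusted p = 0.84). Of 6 glutathione transferase genes 2 rose, or 2 with 1 lower over the list alone (adjusted p = 0.595), GSTU6 by 0.47 (SE 0.11) and GST-I by 0.39 (SE 0.11). A dim GSTU6 probe set had 0.05 (adjusted p = 0.789).

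Among developmental regulators, the flowering time and clock list had 5 of 20 lower and 3 higher, with the same counts over the list alone (adjusted p = 0.429). OsLFL1 and OsHAP3H, both known as repressors of flowering, passed as higher with signals below the array medians in both groups, 33.9 against 10.9 in wild type and 63.8 against 37.4. Their log2 differences of 0.62 (SE 0.07) and 0.46 (SE 0.09) have sizes that depend on the offset. Of 31 MADS-box and floral identity genes 3 fell and 1 rose, with the same counts over the list alone (adjusted p = 0.494). OsMADS50, a promoter of flowering, fell by 0.97 (SE 0.09) and OsMADS57, dim in the mutant (42.1), by 0.81 (SE 0.08). OsMADS56, known as a repressor of flowering and chosen after its values were seen, fell by 1.23 (SE 0.12). Of 54 homeobox genes 4 rose and 2 fell, again with the same counts over the list alone (adjusted p = 0.837); the knotted-class gene Oskn1 rose by 0.78 (SE 0.10) and HOS59 fell by 0.44 (SE 0.08). In the polycomb and chromatin list 6 of 34 rose and 3 fell (7 and 3 over the list alone, adjusted p = 0.416), with rises of 0.93 (SE 0.12) for the arginine methyltransferase gene PRMT10 and 0.63 (SE 0.10) for the DNA methyltransferase gene OsMET1-2.

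Among hormone and cell wall lists, 6 of 34 members of the cytokinin list fell and 3 rose (6 and 5 over the list alone, adjusted p = 0.683). OsVTE2-1, a tocopherol synthesis gene that the symbol match took in, is 1 of the 6, and the cytokinin activation genes LOGL9 and LOGL5 fell by 1.13 (SE 0.13) and 0.89 (SE 0.13). Of 68 auxin genes 3 rose and 3 fell (5 and 5 over the list alone, adjusted p = 0.683), with IAA6 down by a log2 difference of -0.67 (SE 0.12) and ARF17 up by 0.56 (SE 0.12). Of 16 gibberellin genes none passed with limma, over all probe sets or over the list alone, and 2 had an unadjusted p under 0.05 (adjusted p of the list 0.416); SLRL1 had a log2 difference of -0.22 (SE 0.08, adjusted p = 0.139). Of 68 cell wall genes 3 rose and 2 fell (2 and 2 over the list alone, adjusted p = 0.726), with OsEXLA2, an expansin-like gene, at -0.93 (SE 0.09) and OsCslA1, a cellulose synthase-like gene, at 0.57 (SE 0.11).

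The root, seed, photosystem, chlorophyll and photoprotection lists did not pass. Of 49 root-enriched genes 3 fell and 1 rose, with the same counts over the list alone (adjusted p = 0.1). Its members OsNAAT1, a nicotianamine aminotransferase gene of iron uptake, and OsCASPL1U2 fell by 1.24 (SE 0.14) and 0.70 (SE 0.12). Of 19 seed storage and late embryogenesis genes 2 fell, with 2 over the list alone (adjusted p = 0.238), the glutelin gene GLUA-2 by 0.54 (SE 0.09) and the dehydrin gene RAB21 by 0.51 (SE 0.09). A second probe set of each did not pass, with a log2 difference of 0.13 (adjusted p = 0.375) in a dim one for GLUA-2 and -0.24 (adjusted p = 0.0751) for RAB21. Of 9 photosystem and light-harvesting genes 1 fell (2 over the list alone, adjusted p = 0.378), the photosystem I gene OsPSAG by 0.79 (SE 0.12) in 1 probe set, with 0.07 (adjusted p = 0.789) in a dimmer one. Of 20 chlorophyll metabolism genes 2 fell and 1 rose, with the same counts over the list alone (adjusted p = 0.238). The 2 that fell were the chlorophyll breakdown genes OsRCCR1 and OsNYC1, by 0.77 (SE 0.14) and 0.50 (SE 0.09). In the photoprotection and iron list 1 of 9 rose and 1 fell (1 and 3 over the list alone, adjusted p = 0.726). The metallothionein gene OsMT-I-1b fell by 0.81 (SE 0.12), and the member that rose, OsAHP1 (0.43, SE 0.11), encodes a phosphotransfer protein of cytokinin signalling.

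None of the 6 lists that could be tested as first written passed camera, with an unadjusted p under 0.05 in 0 of them and 0 past the threshold with fry or an estimated correlation. Of their members, 5 of 17 jasmonate genes fell and 1 rose (7 and 2 over the list alone), 3 of 31 MADS-box genes fell and 1 rose, 2 of 5 polycomb genes fell, 2 of 6 WRKY genes fell, 2 of 6 defence genes rose, and none of 6 seed genes passed with limma or had an unadjusted p under 0.05. Their adjusted p values ranged from 0.35 to 0.807.

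Of 64 probe sets for reporter and marker sequences, whose identifiers begin with RPTR, 3 rose. The probe set RPTR-Os-K01193-1_at had the largest difference, from 15.2 ± 2.54 in wild type to 9840 ± 197 in the mutant (log2 difference 7.71, SE 0.09, adjusted p = 1.71e-11), where the dim wild-type signal makes the size depend on the offset. It was chosen after its values were seen. The sequences behind these probe sets are not given in the sources used here. Whether the T-DNA of the mutant carries them is not given either. These 3 rises therefore need not be changes of rice transcripts, although they are counted among the 3140 rises and the 208 of at least 2-fold.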

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

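No test of an explanation was run for the control signals in this part, which were examined beside the main comparison because they lie outside the transcripts it covers.

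Of 123 Affymetrix control probe sets, 8 were higher in the mutant than in wild type at an adjusted p of at most 0.05 over the controls (limma), and 16 at an unadjusted p under 0.05. A probe set for 18S ribosomal RNA had a signal of 617.5 ± 47.4 in the mutant and 399.2 ± 39.7 in wild type (SD, n = 3), a log2 difference of 0.593 (SE 0.10, adjusted p = 0.00719). A probe set for 28S ribosomal RNA had 1084 ± 55.5 and 834.8 ± 61.2, a log2 difference of 0.365 (SE 0.09, adjusted p = 0.0418). In both cases all 3 mutant arrays lay above all 3 wild-type arrays, where chance leaves no overlap, in either direction, for 10% of probe sets. The other ribosomal RNA probe sets did not pass: a second for 18S had 0.34 (adjusted p = 0.174), 1 for 25S had 0.22 (adjusted p = 0.503) and 1 for 5.8S had 0.42 (adjusted p = 0.055). The other 6 that passed were 3 of 7 rice actin probe sets (0.35 to 0.40, with 0.22 to 0.43 and adjusted p from 0.122 to 0.651 in the other 4), 2 of 3 cyclophilin probe sets (0.72 and 0.44, with 0.30 and adjusted p = 0.212 in the remaining one) and AFFX-r2-Bs-thr-5_s_at, a probe set for a Bacillus control RNA (1.06, SE 0.14). Other probe sets for thr control RNA had log2 differences from -0.15 to 0.02 and did not pass. All 8 kept their direction under quantile normalization and under subtraction of each array's median, where the 18S difference was 0.62 and 0.58. No biological explanation was tested.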

How the results depend on the processing

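The rebuilt and the further gene lists, with every alternative run on them, were chosen after the gene-name tables had been read, and the SAM-type calls and the 2-fold criterion for single genes after the results were seen. The other alternatives were planned.

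The count of 3140 probe sets that rose lay between 2516 and 4599, and that of 2532 that fell between 1954 and 3425, under both offsets, both scalings, the filters on dim or shared probe sets, no trend, array weights and the SAM-type test on log2 signals. Under quantile normalization 3043 of the rising and 2432 of the falling probe sets were kept. With the replicate number as a replicate block the counts were 2730 and 2385. The numbers were not taken to pair the arrays, as the labels give no pairing. Over all probe sets the deviations of arrays with the same number had correlations of 0.00663, -0.166 and 0.0905. Not every array correlated best with its own number. Among probe sets that fell at least 2-fold the correlation was 0.626, against 0.493 under the closest other matching, so pairing is not excluded for these. The SAM-type test on linear signals gave 3337 that rose and 1485 that fell, and the cause was not tested. A change of at least 2-fold as well left 208 and 249, by its own construction.

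Leaving out 1 array gave 1358 to 3511 probe sets that rose and 916 to 2838 that fell. The counts moved by more than 1.5 times without mutant replicate 2 (1358 and 916), mutant replicate 3 (1716 and 1071) and wild-type replicate 2 (1779 and 1356). The cause was not tested.

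None of the 6 lists tested as first written passed under any alternative, and of all 22 lists rebuilt from symbols 2 passed, neither of which is a version of those 6. Of the rebuilt lists, 4 passed with the replicate block, 1 to 4 when an array was left out, 0 with an estimated correlation and 0 with fry. Without wild-type replicate 3 only 1 passed and the Calvin list had adjusted p = 0.104, within a range up to 0.86 over its alternatives. Without mutant replicate 2, and without wild-type replicate 2, 4 passed. Of the 23 further lists, 0 passed with an estimated correlation and 3 with fry, of which 2 had passed camera. The estimated correlations exceeded the preset 0.01 in all 9 lists that had passed, which widens the test by its construction.

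All 95 probe sets of named genes past the threshold kept their direction in every limma alternative that measured them, and 66 also stayed past it. The SAM-type test called 94 of the 95 on log2 signals and 64 on linear signals, and 33 changed at least 2-fold. Most losses came from leaving out an array: 26 without mutant replicate 2, 24 without wild-type replicate 2, 20 without mutant replicate 3, 12 without wild-type replicate 1, 10 without mutant replicate 1 and 2 without wild-type replicate 3.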

Other observations

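Tests chosen only after the result was seen were the count of splits for the probe sets and for the further lists, the test of root tissue, and the comparison of array order by replicate number. The further lists themselves were added after the gene-name tables were read.

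Among the further lists that missed the threshold, the ethylene list had 4 of 21 members lower (5 adjusted over the list alone, adjusted p = 0.0836), and all 4 were genes of DREB-type cold-response factors: DREB1B, DREB1G, CBF3 and OsDREB1E, with log2 differences of -2.23, -1.80, -1.25 and -0.94. Of 20 heat shock factor genes 3 fell and 1 rose (5 and 2 over the list alone, adjusted p = 0.0801, and 0.0363 with fry). OsHsf-07 fell by 1.94 on the log2 scale whereas OsHsf-25 rose by 1.07 in 1 probe set and fell in the other. Of 28 potassium transport genes 2 fell, OsHAK7 by 0.76 and OsHAK22 by 0.38, with -0.08 (adjusted p = 0.61) in a dim OsHAK22 probe set (2 over the list alone, adjusted p = 0.0512). OsHAK22 missed the threshold when any array but wild-type replicate 3 was left out, with adjusted p from 0.0502 to 0.173. Its log2 differences in those fits lay between -0.44 and -0.3. The genes CBF3, OsDREB1E, OsHsf-25, OsHAK7 and OsHAK22 were chosen after their values were seen.

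Of 64 reporter probe sets, 2 rose besides RPTR-Os-K01193-1_at. Their signals were 295 ± 18.3 in the mutant against 25.4 ± 3.01 in wild type for RPTR-Os-A06498-1_at, and 289 ± 17.6 against 51.5 ± 4.55 for RPTR-Os-A00196-1_s_at (SD, n = 3). No reporter probe set that missed the threshold had a signal above 108 on any array. All 3 mutant arrays carried all 3 signals and no wild-type array did at that level. These probe sets were chosen after their values were seen.

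Splitting the 6 arrays into groups of 3 in every other way gives 10 splits with the real one, too few for a share under 0.05. The real split gave 3140 probe sets in one direction and 2532 in the other, and was the 1 split of 10 to give as many in each. The highest of the others was 0 with limma at the adjusted threshold, and 2981 at an unadjusted p under 0.05 against 12697 for the real split. Every other split mixes the genotypes within its groups, which adds the genotype difference to the spread. Low counts there follow from this and do not support the real counts. For the gene lists, the real split passed 0 lists as first written and the highest other 2, with 10 of 10 splits as large. It passed 2 rebuilt lists and the highest other 7, with 7 of 10 as large, and 7 further lists and the highest other 7, with 2 of 10 as large. Every other split passed at least 1 rebuilt list, so passing camera at the preset correlation is not particular to the genotype grouping. Each of these splits also sets 2 arrays of a genotype against 1, so part of the genotype difference is in it, and what makes the lists pass was not tested.

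A rise of the ribosomal protein list was weighed against 3 technical explanations. The list median of 0.41 lay above the middle 95% of 10000 random lists matched on mean signal, whose upper end was 0.133, which argues against a shift of bright probe sets left by the scaling. The list stayed past the threshold when any 1 array was left out, with a highest adjusted p of 1.42e-06 without wild-type replicate 1, which argues against 1 array that stands apart. Root-enriched genes had a median of -0.071, below the middle range of matched lists (-0.049 to 0.075). This argues against a larger share of root tissue only as far as the list tracks root tissue, which was not checked. Of the 49 root genes, 15 are in another list. A root-enriched median below the matched range is also what a smaller share of root tissue in the mutant samples could give. That explanation was not tested. An effect of the mutation remains a hypothesis, since growth stage was not measured and the list did not pass with an estimated correlation (adjusted p = 0.86).

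Lower signals of calcium signalling genes were weighed in the same way. Leaving out any 1 array kept the list past the threshold, with a highest adjusted p of 0.0243 without wild-type replicate 1, which argues against 1 array that stands apart. The list did not pass with an estimated correlation (adjusted p = 0.477) or with fry (adjusted p = 0.0682). Handling at harvest that differed between the genotypes could give the same pattern: the lowest wild-type array exceeded the highest mutant array by 0.086 in the list's mean log2 signal, which the mutation would also give. Handling and mutation cannot be told apart, because the labels give no harvest times and every array of a group shares its genotype.

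Arrays with the same replicate number stood in the same order in both genotypes for 127 of the 249 probe sets that fell at least 2-fold (51%), where chance gives 16.7% and the highest of the 5 other ways to match the numbers gave 20.5%. The deviations from the group means of these probe sets had a correlation of 0.626 between arrays with the same number and of 0.493 under the closest other matching. OsJAZ13, DREB1B and OsbHLH148, with several-fold differences between arrays of 1 genotype, were among the 8 of 12 named large falls with such an order. Over all probe sets the share was 15.2%, and among those that rose at least 2-fold it was 12.5%. What arrays with the same number shared is not given in the sources used here, and genes that vary together are not independent.

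Genes that differed at least 2-fold were tested for crowding along the chromosomes, as segments from another genetic background would give. Of 271 such genes, the highest number in 100 neighbouring measured genes was 6, on chromosome 8, with a run of near neighbours counted once. Random placement of the same number of genes gave a median of 6, and 0.573 of 10000 placements gave as many. Separate runs thus crowded no more than random placement gave. Counting a run once lowers the number in a segment dense in such genes, so the test cannot exclude such a segment. It also does not exclude single genes near the insertion. By chromosome, between 1.14% and 1.89% of the measured genes differed at least 2-fold.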
